A study of Mus musculus with 8 samples.

How the data were processed

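The series measured RNA in single leukocytes of MC38 tumours in 8 libraries, 1 for each combination of genotype (floxed or TKO), treatment (PBS or anti-PD-1) and sex. The deposited files hold raw UMI counts per gene and barcode, made with Cell Ranger against mm10 from 10x Genomics 5′ libraries of kit version 1. Per the file headers the version was 6.0.0, while the submitters' processing notes name 5.0.0 together with Seurat 4.2.0; the difference could not be resolved from the files. The deposited counts are whole numbers, cover 32285 genes in each library, and hold no barcode under 500 UMIs. Whether barcodes were filtered after Cell Ranger is not stated, and no deposited cell annotation was used here.

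Barcodes with at least 200 genes and at most 15% mitochondrial UMIs were kept, and doublets were predicted per library with Scrublet in scanpy 1.11.5 under Python 3.11.15, with an expected rate proportional to the barcodes of the library (parameter 0.008). Counts were scaled to a common total and log-transformed, 2000 variable genes were reduced to 30 principal components, and a graph of 15 neighbours was clustered with Leiden at resolution 1. T cell receptor and immunoglobulin segments, sex-linked and mitochondrial genes were left out of the variable genes. The 21 clusters were named by fixed marker lists. T cells and proliferating cells were clustered again (1500 genes, 20 components) into 9 clusters and assigned to CD8 T cells (Cd8a or Cd8b1 in at least 0.7 of the cells), regulatory T cells (Foxp3 in at least 0.4), NK cells or other T cells. CD4 conventional T cells, planned as a class, could not be named, because no cluster met the rule. Clusters in which at least 0.5 of the barcodes held Cd3 or Ncr1 with at least 3 UMIs of the myeloid genes Lyz2, C1qa and C1qb were set apart as mixed. The thresholds for naming T cell clusters, mixed clusters and clusters of low depth were set after the clusters were seen. The marker gate took barcodes with a Cd3 UMI, a Cd8a or Cd8b1 UMI and no Cd4 UMI, and for a check of depth barcodes with at least 3000 UMIs were thinned to that number.

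Counts were summed per library and class (pseudobulk) and tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr on the 4 groups, glmQLFit and glmQLFTest, a Benjamini-Hochberg adjusted p under 0.05, and a minimum of 20 cells per library. Averaged effects used sex, treatment and genotype as additive terms (4 libraries against 4), and effects within a group and interactions used the 4 groups plus sex. The replicate numbers follow sex, so the sex term is the replicate block; correlations between the log ratios of pairs of groups ran from -0.0807 to 0.124 in macrophages and monocytes and from -0.029 to 0.197 in NK cells, so the pairing beyond sex is weak. Class shares were tested with the same functions on cells per class and library, without composition factors or dispersion trend, over 10 classes, with an exact two-sided permutation test over the 70 assignments beside it (smallest p 0.0286). DESeq2 1.42.0 was the other tool for genes; a gene is said to pass, rise or fall by edgeR unless DESeq2 is named.

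Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01), with an estimated correlation and with fry beside it. The 21 fixed lists were miR-155 targets, cytotoxic effector, exhaustion and inhibitory receptors, naive, memory and stem-like T cell, type I interferon response, interferon gamma response, cell cycle, T cell activation, glycolysis, oxidative phosphorylation, hypoxia, stress and dissociation, regulatory T cell, Th1 and Tfh, immunostimulatory macrophage, immunosuppressive macrophage, MHC class II presentation, chemokines and receptors, and RNA of myeloid cells, of B cells and of tumour, stromal and red cells. Some share members: Ccl5 stands on the cytotoxic, Th1 and immunostimulatory lists, and Cxcr6 on the exhaustion and chemokine lists. Seed matches to miR-155-5p were searched in the longest annotated 3′ UTR of GENCODE vM21; 20854 genes had one, 628 of them with an 8mer and 16760 without a match.

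The comparisons, tests, lists and most alternatives were fixed before the data were examined. Named genes were, per comparison, the 12 highest and 12 lowest log2 fold changes among genes that passed, moved the same way in every matched pair and had a mean of at least 20 CPM; where fewer than 5 passed in a direction, those with the smallest p; up to 4 passing members of a list, or 2 as values; and genes of a short set for CD8 T cells and macrophages, whether they passed or not. Receptor segments, mitochondrial, ribosomal and clone-named genes were left out of the first 2 parts of the rule. Chosen after the data were seen were the NK cell comparisons, the exact test of the interferon gamma list per library, the list tests in macrophages and NK cells, the interaction tests in these classes, regulatory T cells with at least 8 cells, gated CD8 T cells with at least 10 cells, the gate over all barcodes, T cells as denominator, the fits without barcodes that hold T cell UMIs, and the seed test outside CD8 T cells.

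No TKO library had 20 CD8 T cells. The designed comparisons of CD8 T cells between genotypes, the interaction, anti-PD-1 within TKO mice, the list and seed tests of CD8 T cells by genotype could therefore not be fitted, and the averaged effect of anti-PD-1 in CD8 T cells reduced to that in floxed mice.

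The tests were checked on simulated data in which 200 genes of the real pseudobulk counts were changed. For 2-fold and 4-fold changes, 36.8% and 79.3% were recovered in CD8 T cells, 38.9% and 90.2% in regulatory T cells, 68.4% and 96.8% in macrophages and monocytes and 74.7% and 95.7% in NK cells. Among the genes left unchanged, 1 was called in CD8 T cells, 8 in regulatory T cells, 13 in macrophages and monocytes and 20 in NK cells. In the last 3, where genotype was simulated, these false calls came beside 35 and 83, 67 and 92, and 74 and 89 recovered genes; their number is similar to or above that of the genes called in the real data (6, 15 and 7). Alternatives were leaving out each library, no replicate block, a stricter cell filter (500 genes, 10% mitochondrial UMIs), Leiden resolution 0.5, doublets kept, the same number of cells per library, DESeq2 and its size factors, no filter on low counts, the CD8 marker gate, no proliferating clusters, and TMM over classes.

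Depth per library was 3956660 to 24756605 UMIs. Shares of single libraries carry Wilson 95% intervals, and a count of 0 a floor of 3 counts.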

Results

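Live CD45+ cells, that is leukocytes, were sorted from subcutaneous MC38 tumours, which derive from a mouse colon carcinoma line, and profiled by droplet single-cell RNA sequencing from the 5′ end of transcripts. The series holds 8 libraries in 4 groups of 2. Mice carried floxed miR-155 alleles without Cre (floxed) or with Cd4-driven Cre (TKO), which deletes floxed sequence in the T cell lineage, and received the vehicle PBS or an antibody against the inhibitory receptor PD-1. Tumours grew for 14 days, injections were given on days 7 and 10, and each library pooled 6 to 8 mice. Within each group replicate 1 came from males and replicate 2 from females, so each combination of genotype, treatment and sex had a single library.

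The files held 355 to 2054 barcodes per library (7281 in all), which is 5.92% to 34.2% of the 6000 cells aimed for. Total UMIs per library ran from 3956660 to 24756605 and the median per barcode from 8776 to 10458 UMIs. After filters and removal of 51 predicted doublets, 7004 barcodes were kept. Macrophages and monocytes made up 40.9% of them, NK cells 19.7%, CD8 T cells 5.61%, dendritic cells 4.41%, other T cells 3.16% and regulatory T cells 2.98%. The transcript of Xist was at 207 to 248 CPM in the 4 libraries labelled female and at 0 to 0.149 CPM in those labelled male, and Y-linked Ddx3y at 0 to 0.365 CPM against 33.8 to 39.5 CPM, so no library contradicted its sex label.

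The comparison of genotypes asks what loss of miR-155 from T cells does to the immune cells of the tumour. CD8 T cells were scarce in TKO tumours. They made up 13.0% ± 7.38 (SD, n = 4) of the sorted cells in floxed libraries and 0.280% ± 0.226 (SD, n = 4) in TKO libraries, a log2 fold change of -5.23 (95% CI -6.73 to -3.72; edgeR adjusted p = 0.000559 over 10 classes). The share was lower in the TKO library of 4 of 4 matched pairs, and an exact two-sided permutation test gave p = 0.0286, the smallest that 4 libraries against 4 allow; adjusted over the classes this became 0.0952.

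Single floxed libraries ranged from 4.40% (34 of 773 barcodes, Wilson 95% interval 3.16 to 6.08) in the PBS male library to 22.4% (92 of 410, interval 18.7 to 26.7) in the PBS female library. The TKO libraries held 1 of 334, 3 of 1123 and 11 of 1988 such cells, and the PBS female TKO library 0 of 385, which allows a share of up to 0.779%. These intervals and floors cover counting error only. Log2 fold changes without each library in turn ran from -5.83 to -4.55, and each passed the test.

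**Figure D1:**
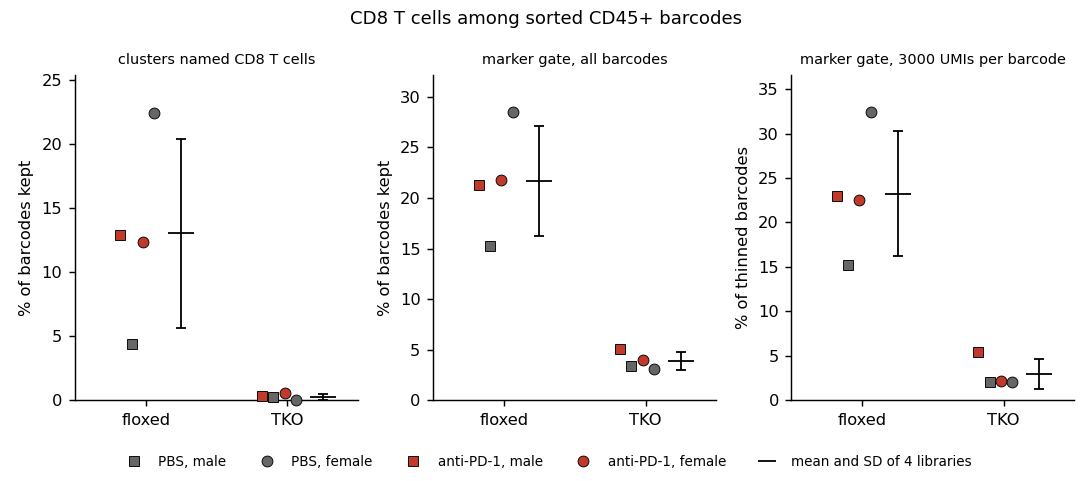
Share of CD8 T cells among barcodes per library in percent, from clusters (left), from a marker gate over all barcodes (middle) and from the same gate after thinning to 3000 UMIs (right). Squares are male and circles female pools, grey is PBS and red anti-PD-1, and bars are the mean and SD of 4 libraries; in each panel every TKO library lies below every floxed one.

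A marker gate that ignored clusters gave a smaller difference in the same direction. Barcodes with Cd3 transcripts, transcripts of Cd8a (mm10 chromosome 6, 71373427 to 71379173) or of its neighbour Cd8b1 (71322788 to 71337494), which encode the chains of the CD8 co-receptor, and no Cd4 were 21.7% ± 5.43 (SD, n = 4) of floxed and 3.90% ± 0.878 (SD, n = 4) of TKO barcodes (log2 fold change -2.48, edgeR adjusted p = 0.000145; exact permutation p = 0.0286). Of the gated barcodes 447 of 663 in floxed and 67 of 147 in TKO libraries lay outside the mixed barcodes, those with lymphoid and myeloid transcripts, and these made up 15.2% ± 7.18 and 1.87% ± 0.399 of the barcodes (SD, n = 4; exact permutation p = 0.0286). In macrophages and monocytes, which should lack these genes, 1.38% ± 1.47 of floxed and 0.315% ± 0.253 of TKO cells passed the gate (SD, n = 4; exact permutation p = 0.171). The median depth was 9725 UMIs over all macrophages and monocytes and 9547 UMIs over CD8 T cells. Within T cell clusters the gated share was 13.9% ± 7.31 against 1.204% ± 0.461 (SD, n = 4; exact permutation p = 0.0286). Of the 405 gated floxed cells there, 87.9% lay in CD8 T cell clusters and 11.4% in clusters of other T cells. Of the 42 gated TKO cells, 26.2% and 66.7% did.

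Transcripts of Mir155hg, the host gene of miR-155 (mm10 chromosome 16, 84703167 to 84715245, plus strand), were not detected in TKO T cells. T cells of the 3 classes had 9.09 ± 1.61 CPM in floxed libraries (SD, n = 4; 49 UMIs) and 0 UMIs in 4 of 4 TKO libraries, at least 2.78-fold lower against a floor of 3 counts over the group (exact permutation p = 0.0286). These pooled T cells are mostly CD8 T cells in floxed libraries, except floxed PBS replicate 1 (34 of 88), and not in TKO libraries. In regulatory T cells alone the counts were 10 UMIs in 3 of 4 floxed libraries and 0 UMIs in TKO libraries, at least 1.36-fold lower (exact permutation p = 0.143). In NK cells, where this Cre is not expected to act, the values were 8.55 ± 2.92 and 6.96 ± 3.04 CPM (SD, n = 4; exact permutation p = 0.486), and in macrophages and monocytes 2.44 ± 0.505 and 3.43 ± 1.68 CPM (SD, n = 4; exact permutation p = 0.314). The labels do not give which part of the gene the floxed sites flank.

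Macrophages and monocytes were the largest class in each genotype, with 32.2% ± 8.03 of floxed and 48.9% ± 2.75 of TKO barcodes (SD, n = 4), and stood higher in the TKO library of 4 of 4 pairs. Their log2 fold change of 0.63 had an adjusted p of 0.0855 and did not pass. Nor did those of dendritic cells (3.26% ± 0.534 and 5.61% ± 0.778; log2 fold change 0.78), regulatory T cells (4.78% ± 1.10 and 2.25% ± 1.30; -1.24) and neutrophils (1.66% ± 0.903 and 0.725% ± 0.463; -1.39), each with the same adjusted p. Macrophages and dendritic cells each had an exact permutation p of 0.0286, the smallest possible, or 0.0952 adjusted. Other T cells (-0.58, adjusted p = 0.202), NK cells (0.07, 0.857), migratory dendritic cells (0.97, 0.147), B cells (0.15, 0.857) and basophils (-0.41, 0.857) did not pass either. Of the 10 classes, CD8 T cells alone passed in edgeR. Without the TKO anti-PD-1 library, replicate 1, or without the floxed anti-PD-1 library, replicate 2, 2 classes passed.

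**Figure D2:**
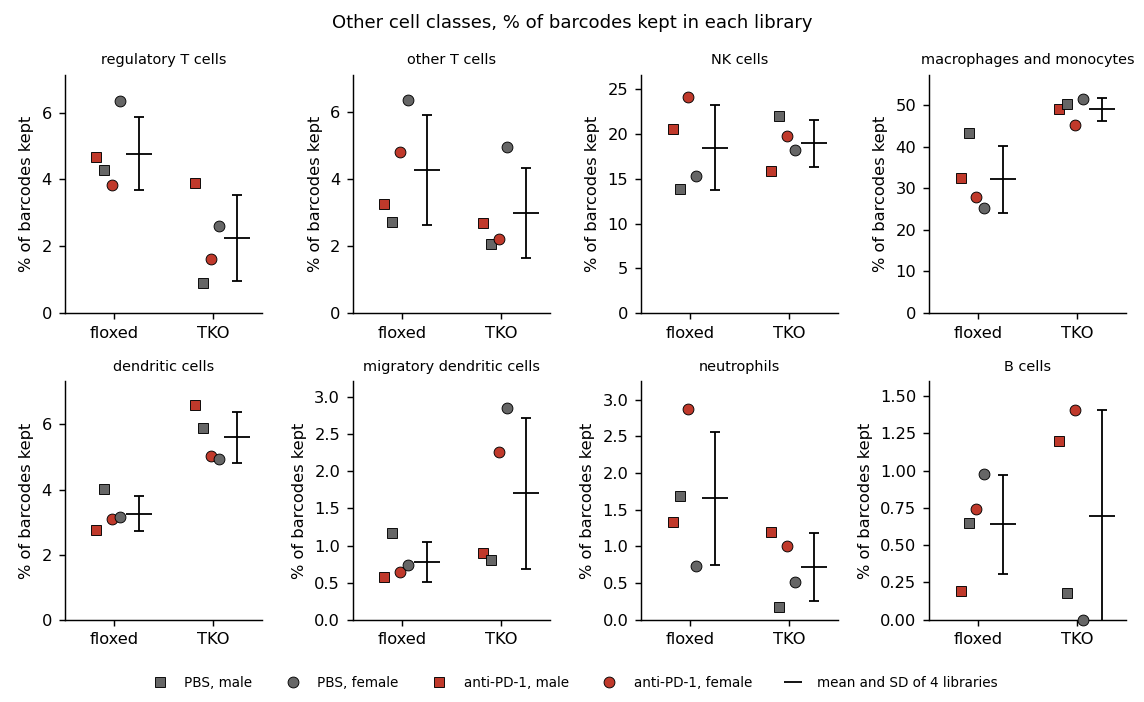
Share of 8 other cell classes among barcodes per library in percent, floxed against TKO. Squares are male and circles female pools, grey is PBS and red anti-PD-1, and bars are the mean and SD of 4 libraries; macrophages and monocytes and dendritic cells have every TKO library above every floxed one, and neither passed the adjusted test.

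Because no TKO library held 20 cells in CD8 T cell clusters, gene expression of CD8 T cells could not be compared between genotypes as designed. A substitute chosen after the data were seen used gated cells of all T cell clusters in the 4 floxed libraries and the 2 TKO libraries with at least 10 such cells. These TKO libraries were PBS male (15 cells) and anti-PD-1 female (18 cells), so treatment and sex cannot be told apart within TKO. The floxed libraries held 41 to 146 such cells, and the fit leaves 2 residual degrees of freedom. In the few gated cells of TKO tumours granzyme and perforin genes fell and Tcf7 rose; no gene list was tested in these cells. The cytotoxic genes Gzmb (log2 fold change -2.55 ± 0.16 SE, adjusted p = 2.85e-10) and Prf1 (-2.94 ± 0.28, adjusted p = 3.25e-07), encoding granzyme B and perforin, fell, as did Gzma (-3.28 ± 0.33), Gzmc (-3.35 ± 0.39) and Gzmf (-5.02 ± 0.39; 0 CPM in 1 of the 2 TKO libraries). Gzmd (-5.66 ± 0.77) fell in edgeR and was not called by DESeq2 (adjusted p = 0.579). The inhibitory receptors Pdcd1 (-1.98 ± 0.25), the gene of PD-1 itself, and Lag3 (-2.13 ± 0.24) fell in both tools. The chemokine receptor Cxcr6 fell as well (-1.54 ± 0.19). Havcr2 (-1.43 ± 0.36) and the exhaustion factor Tox (-2.03 ± 0.50) fell in edgeR and were not called by DESeq2 (adjusted p = 0.215 and 0.173). The cytokine gene Tnf (2.86 ± 0.37), which is on the cytotoxic list, rose mostly through 1 TKO library (447 CPM, against 58.4 CPM in the other and 30.1 to 39.6 CPM in floxed libraries). The chemokine gene Xcl1 (2.06 ± 0.35) rose, and so did the NK receptor genes Klra1 (4.60 ± 0.51) and Klra3 (2.76 ± 0.56). Tcf7, a transcription factor of naive and stem-like cells (3.57 ± 0.34, adjusted p = 3.25e-07), Ccr7 (2.89 ± 0.32) and S1pr1 (2.94 ± 0.49), which guide cells to and out of lymph nodes, Klf2 (2.003 ± 0.27) and Bcl2 (1.53 ± 0.20) rose. Ifng (-1.28 ± 0.42, adjusted p = 0.155), Mki67 (0.48 ± 0.31, adjusted p = 0.609), Ccl5 (-1.08 ± 0.34, adjusted p = 0.127), Isg15 (0.05 ± 0.19) and the miR-155 targets Socs1 (0.14 ± 0.21) and Inpp5d (-0.38 ± 0.40) did not pass in edgeR or DESeq2, nor did Slamf6 (0.24 ± 1.46) in edgeR.

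Of 8298 genes tested in these gated cells, 70 rose and 99 fell in edgeR with the replicate block for sex, and 972 had an unadjusted p under 0.05. Without the block 105 genes passed, and DESeq2 called 103. Without the floxed anti-PD-1 library, replicate 1, the count was 82, without floxed PBS replicate 1 it was 284, and without floxed PBS replicate 2 it was 85. The gated cells of the genotypes differ in the clusters they come from, as given above, so these counts hold differences in subset as well as in state. Tcf7, Ccr7, S1pr1 and Klf2, which rose, are among the genes most raised in a cluster of other T cells. Gzmf and Prf1, which fell, are among those of a CD8 T cell cluster. The named genes thus do not show a change of state within CD8 T cells.

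The comparison of treatments asks what PD-1 blockade changed. No class changed its share with anti-PD-1 in edgeR: 0 of 10 classes passed, 0 had an unadjusted p under 0.05, and an exact permutation test also called 0. CD8 T cells were at 6.78% ± 10.6 under PBS and 6.53% ± 7.06 under anti-PD-1 (SD, n = 4), a log2 fold change of 0.38 with an adjusted p of 0.864. Without floxed anti-PD-1 replicate 1 the log2 fold change was -0.27, and without floxed PBS replicate 1 it was -0.21. In floxed mice the share was 4.40% under PBS and 12.9% under anti-PD-1 in males, but 22.4% and 12.4% in females. The floxed pools thus moved in opposite directions, and the averaged effect has no clear direction. No class had a genotype by anti-PD-1 interaction that passed in edgeR (smallest adjusted p = 0.175, for B cells, whose unadjusted p was 0.0175). No difference of either effect between the sexes passed in edgeR. Its smallest adjusted p was 0.399, for migratory dendritic cells by genotype (unadjusted p = 0.0399). For CD8 T cells the effect of anti-PD-1 differed by 1.75 on the log2 scale between the sexes (unadjusted p = 0.127). Each combination of genotype, treatment and sex had 1 library, so alike effects in the sexes are not shown.

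CD8 T cells could be compared between treatments in floxed mice, with 34 to 136 cells and 292452 to 1547159 UMIs per library. Under anti-PD-1 the granzyme genes parted in edgeR, in a fit with 1 residual degree of freedom. Gzmc (mm10 chromosome 14, 56231441 to 56234656; log2 fold change 1.99 ± 0.20 SE, adjusted p = 1.03e-19) and Gzmf (1.35 ± 0.19, adjusted p = 1.41e-09) rose, as did Prf1 (0.84 ± 0.18, adjusted p = 0.000857), whereas Gzma (chromosome 13, 113093825 to 113100981; -1.91 ± 0.19, adjusted p = 4.84e-20) and Gzmk (-0.97 ± 0.19, adjusted p = 0.000193) fell. The secreted factors Csf2, which encodes GM-CSF (-2.45 ± 0.32; 13.2 and 143 CPM under PBS, 3.27 and 24.9 CPM under anti-PD-1), and the chemokines Xcl1 (-1.81 ± 0.23) and Ccl5 (-1.64 ± 0.19) fell. The cell cycle inhibitor Cdkn1a (2.42 ± 0.44; mostly through 1 library at 65.4 CPM, against 11.1 CPM in the other and 6.61 and 10.1 CPM under PBS), the decoy interleukin-1 receptor Il1r2 (1.42 ± 0.23) and the metallothionein Mt1 (1.29 ± 0.22) rose. Gzmf, Prf1 and Mt1 are among the genes most raised in 1 cluster of these cells, and Gzmk and Ccl5 in another. The first held 27 of 136 and 35 of 116 cells under anti-PD-1, against 4 of 34 and 15 of 92 under PBS. The second held 58 of 136 and 46 of 116, against 17 of 34 and 44 of 92. Csf2, which fell, and Il1r2, which rose, are both among those of a further cluster. Changes between and within clusters were not separated.

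Of 7892 genes, 35 rose and 30 fell (n = 2 libraries against 2), and 28 of these 65 were T cell receptor segments, which differ between pools of mice by clone. Unadjusted p was under 0.05 for 524 genes. DESeq2 called 4 genes, 4 of them among the 65: Gzma, Ccl5, Gzmf and a receptor segment. It did not call Gzmc (adjusted p = 0.220), Prf1 (0.276), Xcl1 (0.105), Csf2 (0.564) or the other genes named above. The model leaves 1 residual degree of freedom, so its SEs and p-values say little about the spread between pools of mice. Without the replicate block for sex 3 genes passed. With the same number of cells taken from each library the count was 25, and without proliferating clusters 39. Pdcd1 (0.05 ± 0.18, adjusted p = 0.997), Gzmb (-0.06 ± 0.19, adjusted p = 0.994), Ifng (0.05 ± 0.19, adjusted p = 0.997) and the proliferation gene Mki67 (-0.40 ± 0.22, adjusted p = 0.789) did not pass. Nor did Havcr2 (0.42 ± 0.20, adjusted p = 0.663), Tox (-0.20 ± 0.21), Isg15 (-0.14 ± 0.18), Cxcr6 (-0.11 ± 0.18), Socs1 (-0.38 ± 0.19) or Inpp5d (-0.43 ± 0.24). Mir155hg, Tcf7 and Slamf6 had too few counts to be tested.

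**Figure D3:**
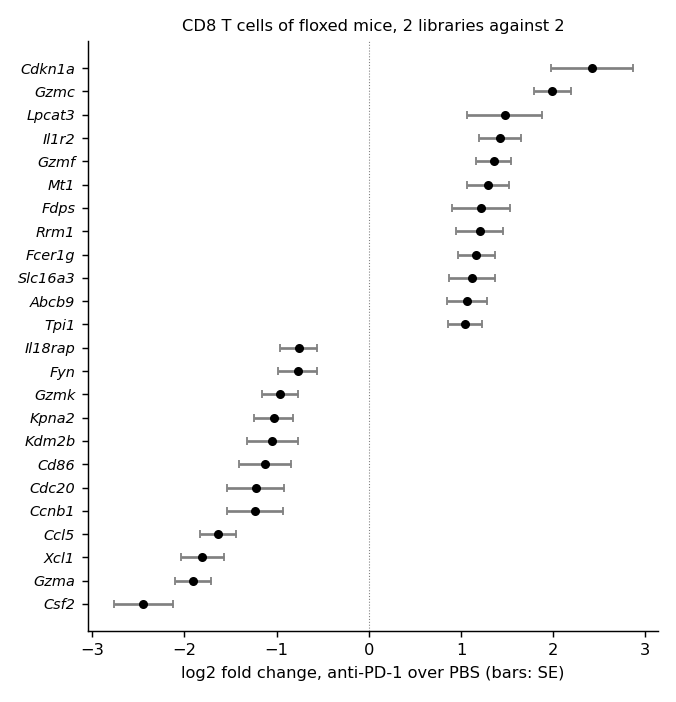
Log2 fold change (horizontal axis, bars are the SE) of 12 risen and 12 fallen genes in CD8 T cells of floxed mice, anti-PD-1 over PBS, 2 libraries against 2. They have the highest and lowest changes among genes open to the naming rule, which leaves out T cell receptor segments, some with larger changes. Values run from -2.45 for Csf2 to 2.42 for Cdkn1a.

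By fixed gene lists, glycolysis had the smallest camera p in these CD8 T cells, while the immunostimulatory macrophage list had a larger mean change (-0.73 against 0.57). Of 14 tested glycolysis genes 2 rose (Tpi1 1.04 ± 0.19 and Slc16a3, a lactate exporter, 1.12 ± 0.25) and 0 fell, and 11 rose when adjusted over the list alone (camera adjusted p = 9.07e-17; adjusted p = 0.485 with an estimated correlation). The cytotoxic list was split, with 3 of 26 members risen and 3 fallen, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.189). The cell cycle list was split as well, with 3 of 40 risen, among them Rrm1 (1.201 ± 0.26) and Mcm3 (0.81 ± 0.22) of DNA synthesis, and 2 fallen, Ccnb1 (-1.24 ± 0.31) and Cdc20 (-1.23 ± 0.31) of mitosis. Adjusted over the list alone these were 6 and 5 (camera adjusted p = 0.814). Its mean log2 fold change of -0.01 and median of -0.10 differ in sign from the test, which points up.

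Fry called 0 lists in these cells. Hypoxia rose as a list (adjusted p = 0.000346; adjusted p = 0.485 with an estimated correlation) with 0 of 9 members passing and 1 risen adjusted over the list alone. The regulatory T cell list rose (adjusted p = 0.00341; adjusted p = 0.485 with an estimated correlation) with 1 of 12 risen, the costimulatory receptor Tnfrsf4 (0.90 ± 0.21, but -0.32 with an adjusted p of 0.900 in cells taken by the CD8 marker gate), and 4 adjusted over the list alone. The exhaustion (adjusted p = 0.0105) and oxidative phosphorylation lists (adjusted p = 0.0162) rose with 0 members passing either way, each with an adjusted p = 0.485 with an estimated correlation. Interferon gamma genes fell as a list (adjusted p = 0.00992; adjusted p = 0.485 with an estimated correlation) with 0 of 34 passing and 1 risen and 1 fallen adjusted over the list alone. Type I interferon (adjusted p = 0.0105), miR-155 target (0.0132) and chemokine genes (0.0226) fell as lists with 0 members passing either way, each with an adjusted p = 0.485 with an estimated correlation. The Th1 and Tfh list fell (adjusted p = 0.00175; adjusted p = 0.485 with an estimated correlation) with 2 of 9 fallen, also adjusted over the list alone: Ccl5 and the interleukin-18 receptor chain Il18rap (-0.76 ± 0.20). The immunostimulatory macrophage list fell (adjusted p = 2.97e-05; adjusted p = 0.485 with an estimated correlation) with 2 of 6 fallen, Ccl5 and the costimulatory ligand Cd86 (-1.13 ± 0.28), and 3 adjusted over the list alone.

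RNA of myeloid cells rose in the same CD8 T cells (adjusted p = 0.00175; adjusted p = 0.485 with an estimated correlation) with 1 of 8 risen, Fcer1g, a signalling chain that some T cells also express (1.17 ± 0.20), and 3 risen and 1 fallen adjusted over the list alone. The fallen gene, Lyz2, was at -1.08 (adjusted p = 0.418). T cell activation (adjusted p = 0.0705; Tnfrsf4, with the reversal given above, rose and Xcl1 fell, also over the list alone), MHC class II (0.141), immunosuppressive macrophage (0.189), naive and memory (0.554) and stress genes (0.554) did not pass.

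Regulatory T cells are expected to have the Cre active as well. With at least 20 cells per library, 4 floxed libraries and a single TKO library entered, replicate 2 of TKO anti-PD-1, so that fit gives no result on genotype. The 27 of 3785 genes that set this library apart are left without names, and 1 of them was called by DESeq2.

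With at least 8 cells per library, a limit chosen after the data were seen, 4 libraries of each genotype entered. The floxed libraries held 26 to 49 regulatory T cells and the TKO libraries 10, 10, 13 and 32, so few cells stand behind the TKO values. Prf1 (1.01 ± 0.57, adjusted p = 0.793), Ccl5 (0.34 ± 0.52, adjusted p = 0.928) and Isg15 (-0.48 ± 0.26, adjusted p = 0.793) did not pass there. Ecm1, an extracellular matrix protein of T cell migration (1.22 ± 0.23; 325 ± 125 against 762 ± 79.1 CPM, SD, n = 4), rose in TKO regulatory T cells in 4 of 4 pairs, as did the mitochondrial genes mt-Co1 (0.99 ± 0.17), mt-Atp6 (1.14 ± 0.21) and mt-Co3 (1.17 ± 0.23), whose RNA also varies with cell quality. Spp1 (2.89 ± 0.53) and the neutrophil gene Ltf (4.72 ± 0.91) rose in 3 of 4 pairs. Spp1 did so mostly through the TKO anti-PD-1 libraries (7404 and 2072 CPM, against 281 and 27.2 CPM in TKO PBS libraries and 30.5 to 740 CPM in floxed ones). Ltf did so through the TKO PBS libraries (309 and 1497 CPM, against 0 and 19.9 CPM under anti-PD-1 and 0 to 24.6 CPM in floxed libraries). These 6 of 2757 genes rose and 0 fell in edgeR (200 at an unadjusted p under 0.05). DESeq2 called 6 genes, 4 of them the same, but not Spp1 (adjusted p = 0.604) or Ltf (adjusted p = 0.9991). Without floxed anti-PD-1 replicate 1 the count was 11, without floxed PBS replicate 2 it was 16, and without TKO anti-PD-1 replicate 2 it was 13. The genes also changed. Of the 6, 3 stayed called without floxed PBS replicate 1, floxed anti-PD-1 replicate 2 or TKO anti-PD-1 replicate 1. Only 1 stayed called without TKO PBS replicate 2, where the count was 6, and only 1 with the same number of cells per library.

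Under anti-PD-1, Spp1, which encodes the secreted protein osteopontin and is also on the list of myeloid RNA, rose in regulatory T cells with at least 8 cells per library (4.46 ± 0.56, adjusted p = 0.000951; 95.0 ± 124 CPM under PBS and 2611 ± 3289 CPM under anti-PD-1, SD, n = 4), in 4 of 4 pairs. It was the only gene of 2757 that passed in edgeR (92 at an unadjusted p under 0.05) and DESeq2 called 1. Each omission of a library gave more genes. The count was 4 without floxed anti-PD-1 replicate 1, floxed anti-PD-1 replicate 2 or TKO PBS replicate 2, and 2 without floxed PBS replicate 1. It was 5 without TKO anti-PD-1 replicate 1 or replicate 2, 6 without TKO PBS replicate 1 and 9 without floxed PBS replicate 2. With at least 20 cells, 9 of 3785 genes rose, among them Spp1 (3.61 ± 0.41), the chemokine Ccl4 (1.29 ± 0.15), Prf1 (2.14 ± 0.41) and the transcription factor Irf8 (1.41 ± 0.32). There 11 fell, among them Cd8b1 (-3.76 ± 0.53), Gzmk (-3.53 ± 0.93), Gzmc (-2.70 ± 0.49) and Ly6c2 (-1.10 ± 0.22). Of these 8 named genes Spp1 alone passed with at least 8 cells. Cd8a fell with Cd8b1 (146 ± 9.80 CPM under PBS, SD, n = 2, and 0 CPM in 3 of 3 libraries under anti-PD-1). With at least 8 cells it was at 160 and 144 CPM in the floxed PBS libraries and 0 CPM in every other library, TKO PBS included. The genes of both CD8 chains thus moved together in this pool, whereas the cytotoxic gene Prf1 rose, as given above. Cd8a, Cd8b1, Gzmk and Ly6c2 are among the genes most raised in a CD8 T cell cluster. Of the barcodes named regulatory T cells 83.7% held Foxp3 and 11.0% Cd8a or Cd8b1 transcripts. Whether CD8 T cells within the class lie behind these falls was not tested. Of the 20 genes, 5 were T cell receptor segments. The single TKO library is taken up by the genotype term, so the fit with 20 cells rests on 2 floxed libraries against 2. DESeq2 called 1 there, the fit without the replicate block 5, and the fit without TKO anti-PD-1 replicate 2 gave 6.

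In macrophages and monocytes the Cre is not expected to be active, so their comparison asks what changes around the T cells. In TKO tumours 3 of 36 tested genes of the interferon gamma list fell in them in edgeR; without the replicate block 0 genes passed, and the call of the list is lost with an estimated correlation (adjusted p = 0.243). The guanylate-binding proteins Gbp4 (mm10 chromosome 5, 105115767 to 105139586; log2 fold change -0.78 ± 0.12 SE; 156 ± 29.6 against 90.2 ± 12.03 CPM, SD, n = 4) and Gbp6 (-0.63 ± 0.10), the protease inhibitor Serpina3g (-1.16 ± 0.19; 45.3 ± 13.8 against 19.7 ± 3.98 CPM) and Nos2, the inducible nitric oxide synthase (-1.56 ± 0.24; 14.2 ± 5.35 against 4.30 ± 2.96 CPM), fell in 4 of 4 pairs. Ifitm1, an interferon-induced membrane protein (-1.23 ± 0.16), Cnn3 (-0.91 ± 0.14), Gpr171 (-0.86 ± 0.14) and AA467197 (-0.79 ± 0.13) fell too, and Cd63, a tetraspanin of late endosomes (0.85 ± 0.11), and the lysozyme gene Lyz1 (1.97 ± 0.33; 74.3 CPM in 1 TKO library, 6.14 to 16.1 CPM in the other 3 and 2.05 to 9.99 CPM in floxed ones) rose. T cell transcripts fell with them: Cd3g (-2.50 ± 0.28), Cd3e (-2.35 ± 0.35) and Cxcr6 (-3.27 ± 0.48), the first pair named after their values were seen. Of macrophages and monocytes, 15.7% ± 9.57 in floxed and 3.87% ± 1.12 in TKO libraries held a T cell UMI (SD, n = 4; exact permutation p = 0.0286).

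Of 9565 genes 2 rose and 13 fell, each in 4 of 4 pairs. Unadjusted p was under 0.05 for 620 genes, and DESeq2 called 39, with the 15 among them. Without floxed PBS replicate 1 the count was 4, without TKO PBS replicate 1 it was 9, without floxed anti-PD-1 replicate 2 it was 4, without floxed PBS replicate 2 it was 3, and without TKO PBS replicate 2 it was 31. Between 2 and 15 of the 15 genes stayed called in these and the other omissions. Without the replicate block the count was 0, and without barcodes that hold T cell UMIs it was 5. The stricter cell filter, Leiden resolution 0.5 and keeping doublets lowered it as well, with counts given in the section on processing choices below. The chemokine Cxcl9 (-0.84 ± 0.16, adjusted p = 0.0899; DESeq2 adjusted p = 0.000322) and the ligand of PD-1, Cd274 (-0.48 ± 0.12, adjusted p = 0.205), did not pass in edgeR, nor did Cxcl10 (-0.09 ± 0.12), Arg1 (-0.9985 ± 0.29, adjusted p = 0.409), Mrc1 (0.13 ± 0.36), H2-Ab1 (-0.24 ± 0.21) or Spp1 (-0.02 ± 0.42).

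**Figure D4:**
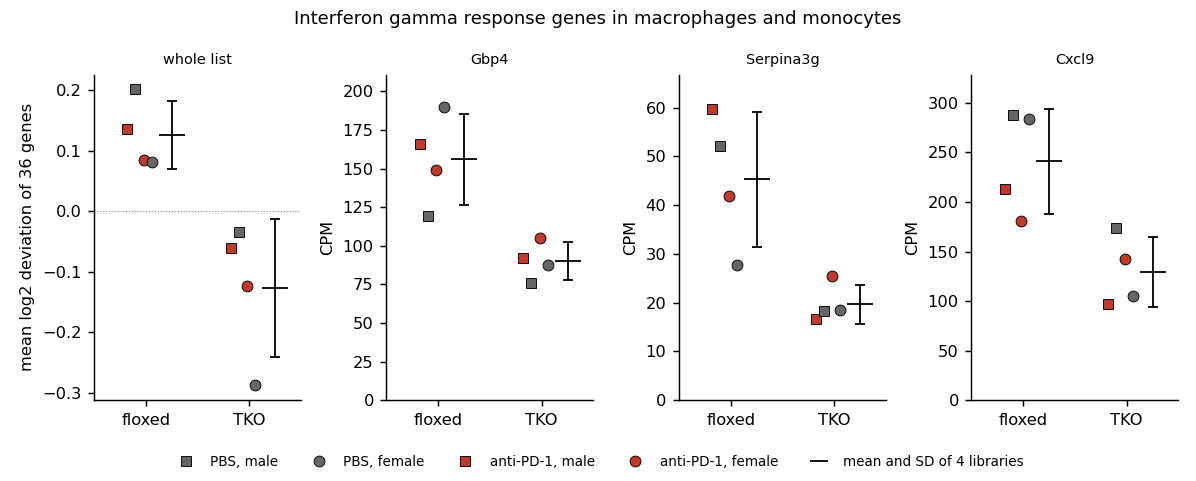
Interferon gamma response genes in macrophages and monocytes per library: the mean log2 deviation of 36 genes from their mean over libraries (left) and the CPM of Gbp4, Serpina3g and Cxcl9. Squares are male and circles female pools, grey is PBS and red anti-PD-1, and bars are the mean and SD of 4 libraries; the 4 floxed libraries lie at 0.0815 to 0.202 and the 4 TKO libraries at -0.288 to -0.0346 on the left.

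Of 36 tested members of the interferon gamma list, 3 fell and 0 rose in edgeR, and 10 fell when adjusted over the list alone. DESeq2 called these 3 and also Cxcl9, Gbp2 and Iigp1, the last pair named after their values were seen. A log2 fold change below 0 was found for 30 (mean -0.25; camera adjusted p = 4.34e-11, adjusted p = 0.243 with an estimated correlation). Averaged over the list, the 4 floxed libraries stood at 0.126 ± 0.0563 and the 4 TKO libraries at -0.126 ± 0.114 on the log2 scale (SD, n = 4; exact permutation p = 0.0286, chosen after the list was seen to move). The immunostimulatory macrophage list fell (adjusted p = 0.0369; adjusted p = 0.573 with an estimated correlation) with 1 of 14 fallen, Nos2, and 3 fallen and 1 risen adjusted over the list alone. Type I interferon genes rose as a list (adjusted p = 2.24e-06; adjusted p = 0.553 with an estimated correlation), with 35 of 40 above 0 and 0 passing either way. Stress genes rose with 0 of 20 passing and 1 risen adjusted over the list alone (adjusted p = 5.32e-05; adjusted p = 0.512 with an estimated correlation). Glycolysis fell with 0 of 14 passing either way (adjusted p = 0.0017; adjusted p = 0.512 with an estimated correlation). Myeloid RNA rose with 0 of 18 passing in edgeR (DESeq2 called Apoe, 0.63, adjusted p = 0.00314), and 1 risen and 1 fallen adjusted over the list alone (adjusted p = 0.00262; adjusted p = 0.243 with an estimated correlation).

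Lists of T cell genes fell in the same macrophages and monocytes. Th1 and Tfh genes had 0 of 7 passing and 1 fallen adjusted over the list alone (adjusted p = 8.95e-05; adjusted p = 0.364 with an estimated correlation). Exhaustion genes had 1 of 15 fallen, Cxcr6, and 3 adjusted over the list alone (adjusted p = 8.95e-05; adjusted p = 0.203 with an estimated correlation). Naive and memory genes had 0 of 14 passing in edgeR, where DESeq2 called Klf2 (adjusted p = 0.000506) and Ltb (adjusted p = 0.00773), and 2 fallen adjusted over the list alone (adjusted p = 0.00154; adjusted p = 0.512 with an estimated correlation).

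In the same comparison hypoxia (adjusted p = 0.0759), T cell activation (0.0827), cytotoxic (0.0834), regulatory T cell (0.102), immunosuppressive macrophage (0.118), MHC class II (0.557), miR-155 target (0.574), cell cycle (0.661), oxidative phosphorylation (0.831) and chemokine lists (0.849) did not pass, and fry called 0 lists. Of their members DESeq2 called Gzmc, Apoe, Ccl2 and Cxcr6, which were looked up after the lists were tested. The chemokine list's mean of -0.36 and median of -0.03, and the oxidative phosphorylation list's mean of -0.00 and median of -0.01, differ in sign from their tests. The miR-155 target list's median of 0.00 differs in sign from its test and its mean of -0.06. The lists of B cell RNA and of tumour, stromal and red cell RNA had too few tested members in this and every other comparison.

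Under anti-PD-1, macrophages and monocytes had less Pltp, which encodes a phospholipid transfer protein (mm10 chromosome 2, 164839518 to 164857711; log2 fold change -0.87 ± 0.11 SE, adjusted p = 0.0418; 95.3 ± 25.8 against 52.0 ± 8.42 CPM, SD, n = 4), lower in 4 of 4 pairs. Of 9565 genes 0 rose and this 1 fell in edgeR, 478 had an unadjusted p under 0.05, and DESeq2 called 4. The count was 0 without floxed anti-PD-1 replicate 1 or 2, floxed PBS replicate 1, TKO PBS replicate 1 or 2 or TKO anti-PD-1 replicate 2, and 2 without floxed PBS replicate 2. Without TKO anti-PD-1 replicate 1 it was 1, which was another gene (Pltp adjusted p = 0.0877), so Pltp stayed called in 1 of 8 omissions. Apoe, of lipid transport (-0.64 ± 0.13, adjusted p = 0.411), the costimulatory receptor Tnfrsf9 (1.44 ± 0.25, adjusted p = 0.312) and the chemokine Cxcl16 (-0.66 ± 0.16, adjusted p = 0.706) did not pass in edgeR, whereas DESeq2 called Apoe (adjusted p = 0.0256). Cxcl9 (-0.36 ± 0.16), Nos2 (0.73 ± 0.25), H2-Ab1 (-0.50 ± 0.21) and Spp1 (-0.67 ± 0.43), which had risen in regulatory T cells, did not pass (adjusted p = 0.959 each). Nor did Cd274 (0.17 ± 0.12), Cxcl10 (0.11 ± 0.13), Arg1 (0.10 ± 0.28) or Mrc1 (-0.40 ± 0.35). Hypoxia rose as a list, with 0 of 13 members passing and 4 risen adjusted over the list alone (camera adjusted p = 1.11e-06; adjusted p = 0.520 with an estimated correlation). Glycolysis (adjusted p = 0.000611), regulatory T cell genes (0.00605; 2 risen adjusted over the list alone) and oxidative phosphorylation (0.00634) rose too, with 0 members passing, each with an adjusted p = 0.520 with an estimated correlation. MHC class II genes fell with 10 of 10 below 0 and 0 passing (0.00634; adjusted p = 0.638 with an estimated correlation). Fry called 0 lists. The number of lists was 9 without floxed anti-PD-1 replicate 1 or TKO anti-PD-1 replicate 2, and 8 without TKO PBS replicate 1 or floxed PBS replicate 2. The lists of immunosuppressive macrophages (adjusted p = 0.0912), chemokines (0.0979), stress (0.102), T cell activation (0.141), myeloid RNA (0.173), miR-155 targets (0.292), naive and memory (0.439) and interferon gamma genes (0.439) did not pass. Nor did exhaustion (0.504), cytotoxic (0.611), type I interferon (0.711), Th1 and Tfh (0.711), immunostimulatory macrophage (0.790) and cell cycle genes (0.790). Of these the mean and median of myeloid RNA (0.02 and 0.01), the median of exhaustion (-0.00) and that of cell cycle genes (0.04) differ in sign from the test. The genotype by anti-PD-1 interaction had 0 genes in edgeR, 432 at an unadjusted p under 0.05 and 0 in DESeq2. Its count was 1 without floxed PBS replicate 1, 6 without TKO PBS replicate 1, and 2 without TKO anti-PD-1 replicate 1 or 2 or floxed anti-PD-1 replicate 2.

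NK cells were added after the data were seen, and the Cre is not expected to act in them. A few genes passed by genotype in edgeR, and which ones depended on single libraries. TKO tumours had NK cells with less Ly6c2 (log2 fold change -0.89 ± 0.12 SE; 1393 ± 305 against 767 ± 228 CPM, SD, n = 4) and Ly6a (-0.64 ± 0.09), surface proteins that interferons induce in lymphocytes, less Il12rb2, a chain of the interleukin-12 receptor (-0.83 ± 0.12; 79.1 ± 12.8 against 46.1 ± 7.06 CPM), and less of the MYC antagonist Mxd1 (-1.07 ± 0.15), Sult2b1 (-0.97 ± 0.16) and the phosphodiesterase Pde2a (-1.49 ± 0.19, named after its value was seen). Ugt1a7c rose (0.85 ± 0.14). Of 9316 genes 1 rose and 6 fell, each in 4 of 4 pairs, 778 had an unadjusted p under 0.05, and DESeq2 called 15, with the 7 among them. Without the replicate block 2 genes passed. Without TKO anti-PD-1 replicate 1 the count was 18, without TKO PBS replicate 1 it was 1, without floxed anti-PD-1 replicate 2 it was 2, without floxed PBS replicate 2 it was 1, and without TKO PBS replicate 2 it was 4. Of the 7 genes, 0 stayed called without TKO PBS replicate 1, 1 without floxed anti-PD-1 replicate 2 or floxed PBS replicate 2, and 2 with the same number of cells per library. NK cells pooled several clusters, and no fit was made within them. Sult2b1 is among the genes most raised in 1 of these clusters. A proliferating cluster held 14 of 216, 15 of 107, 22 of 227 and 7 of 63 NK cells in floxed libraries. In TKO libraries it held 9 of 53, 43 of 248, 66 of 393 and 9 of 70. Changes in subset and in state were not separated.

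As lists, cytotoxic (camera adjusted p = 3.77e-05), exhaustion (3.47e-05) and naive and memory genes (7.09e-06) fell in TKO NK cells with 0 members passing over all genes in edgeR, each with an adjusted p = 0.0556 with an estimated correlation. DESeq2 called the inhibitory receptor genes Lag3 (-0.58 ± 0.10, adjusted p = 0.0239) and Tigit (-0.57 ± 0.10, adjusted p = 0.0435) and the factor Klf2 (-1.26 ± 0.21, adjusted p = 0.000300) of these lists. Adjusted over the list alone, 10 of 27 cytotoxic genes fell and 3 rose, 5 of 19 exhaustion genes fell and 6 of 13 naive and memory genes fell. Fry called the exhaustion and the naive and memory lists. Cell cycle (adjusted p = 2.64e-07; 34 of 40 above 0; adjusted p = 0.376 with an estimated correlation) and oxidative phosphorylation genes (4.91e-07; adjusted p = 0.143 with an estimated correlation) rose with 0 passing either way. MHC class II genes (0.011; adjusted p = 0.243 with an estimated correlation) rose with 0 passing and 1 risen adjusted over the list alone.

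Th1 and Tfh genes fell in the same NK cells with 1 of 10 fallen, Il12rb2, and 2 adjusted over the list alone (adjusted p = 3.47e-05; adjusted p = 0.123 with an estimated correlation). Type I interferon (5.16e-07; adjusted p = 0.143 with an estimated correlation) and hypoxia genes (0.000963; adjusted p = 0.314 with an estimated correlation) fell with 0 passing either way. Interferon gamma genes (0.00114; adjusted p = 0.154 with an estimated correlation) and miR-155 targets (0.0045; adjusted p = 0.143 with an estimated correlation) fell with 0 passing in edgeR and 2 fallen each adjusted over the list alone, while DESeq2 called Fgl2 of the first (adjusted p = 0.00608) and Ifngr1 of the second (adjusted p = 0.0239). Regulatory T cell genes fell with 0 passing and 3 fallen adjusted over the list alone (0.0267; adjusted p = 0.243 with an estimated correlation). T cell activation (adjusted p = 0.380), stress (0.380), chemokine (0.487), glycolysis (0.530), myeloid RNA (0.619), immunostimulatory (0.805) and immunosuppressive macrophage genes (0.934) did not pass. Of these the median of myeloid RNA (0.02), the mean of immunostimulatory (-0.09) and that of immunosuppressive macrophage genes (0.02) differ in sign from the test.

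Under anti-PD-1, 0 of 9316 genes changed in NK cells in edgeR, 415 had an unadjusted p under 0.05, and DESeq2 called 5. Besides Gzma and Gzmd, given below, these were Ccdc184 (-1.275 ± 0.19, DESeq2 adjusted p = 0.000805), Ifitm2 (0.81 ± 0.17, 0.00447) and Ly6a (0.41 ± 0.09, 0.0487). The count in edgeR was 1 without floxed PBS replicate 1, TKO anti-PD-1 replicate 1 or TKO PBS replicate 2, and 2 without TKO PBS replicate 1. Cytotoxic genes rose as a list (camera adjusted p = 1.09e-09, adjusted p = 0.0355 with an estimated correlation), with 0 of 27 passing in edgeR and 3, Gzma, Gzmb and Gzmd, risen adjusted over the list alone. Gzma itself was at 0.56 ± 0.10 (adjusted p = 0.428; DESeq2 adjusted p = 0.00173) and higher in 4 of 4 pairs, and Gzmd had a DESeq2 adjusted p of 0.0487. Type I interferon genes (adjusted p = 1.09e-09; adjusted p = 0.240 with an estimated correlation; 1 risen adjusted over the list alone) and interferon gamma genes (0.000787; adjusted p = 0.240 with an estimated correlation) rose as well. So did glycolysis (0.0152; adjusted p = 0.544 with an estimated correlation), hypoxia (0.0152; adjusted p = 0.522 with an estimated correlation) and myeloid RNA (0.0156; adjusted p = 0.240 with an estimated correlation; 1 risen adjusted over the list alone). Cell cycle genes fell (0.000787; adjusted p = 0.544 with an estimated correlation), and each of these lists had 0 members passing over all genes.

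The number of lists moved in NK cells by anti-PD-1 fell from 7 to 4 without floxed anti-PD-1 replicate 2 or TKO anti-PD-1 replicate 2 and to 3 without floxed PBS replicate 2, and fry called 0. Th1 and Tfh (adjusted p = 0.149), MHC class II (0.149), T cell activation (0.162), exhaustion (0.169), chemokine (0.195) and immunosuppressive macrophage genes (0.365) did not pass. Nor did miR-155 targets (0.365), regulatory T cell (0.365), naive and memory (0.627), stress (0.733), oxidative phosphorylation (0.747) and immunostimulatory macrophage genes (0.875). The means of exhaustion (-0.00) and of naive and memory genes (-0.05) differ in sign from their tests. The interaction had 0 genes in edgeR, 323 at an unadjusted p under 0.05 and 2 in DESeq2. Its count was 1 without floxed PBS replicate 1 and 4 without floxed anti-PD-1 replicate 2 or TKO anti-PD-1 replicate 2.

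Loss of a microRNA is known to raise the transcripts it represses. In regulatory T cells, 87 genes with an 8mer match to the miR-155-5p seed in the annotated 3′ UTR had a median log2 fold change 0.04 above that of 2128 genes without a match (TKO over floxed; exact two-sided test over 35 splits of the 8 libraries, p = 0.629). No shift of the predicted targets was detected there, and without single libraries the difference ran from 0.00917 to 0.0637. Over all genes with a 3′ UTR its median length was 2686.5 nucleotides with an 8mer and 754 without a match, and length was not matched. TKO libraries held 10 to 32 regulatory T cells, so a small shift could be missed. In macrophages and monocytes the difference was -0.01 (315 genes; exact p = 0.514) and in NK cells -0.03 (306 genes; exact p = 0.314); the Cre is not expected to act in these cells, so their values do not bear on the loss of miR-155. This test was moved from CD8 T cells, which were too few in TKO libraries, after the data were seen.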

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

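The alternatives named in the processing section as chosen after the data were seen, and every alternative of the results they concern, were added after the results were seen; the others were planned. The lower CD8 T cell share in TKO libraries passed in each alternative fit with edgeR, but not in the exact permutation test adjusted over classes (p = 0.0286, adjusted 0.0952). Its log2 fold change ran from -5.83 to -4.55 without single libraries, and was -2.48 with the gate over all barcodes and -2.84 with T cells as denominator. Counts of genes moved far more. Unless said otherwise, the cause was not tested. Depth limits the classes with few cells, as libraries held as few as 41031 UMIs of regulatory T cells and 292452 of CD8 T cells.

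Without single libraries, counts ran from 5 to 16 genes (regulatory T cells by genotype, 8 cells), 2 to 9 (regulatory T cells by anti-PD-1, 8 cells), 3 to 31 (macrophages and monocytes by genotype), 0 to 2 (the same by anti-PD-1), 0 to 6 (the same, interaction), 1 to 18 (NK cells by genotype), 0 to 2 (NK cells by anti-PD-1), 0 to 4 (NK cells, interaction) and 82 to 284 (gated CD8 T cells by genotype). Lists ran from 4 to 9 (macrophages and monocytes, anti-PD-1) and from 3 to 7 (NK cells, anti-PD-1), classes changed by genotype from 1 to 2, and the log2 fold change of the CD8 T cell share by anti-PD-1 from -0.27 to 1.51. Regulatory T cells by anti-PD-1 with 20 cells had 6 genes without TKO anti-PD-1 replicate 2; no other library could be left out there, nor any in CD8 T cells of floxed mice, since no residual degree of freedom or no replicate of an arm remained.

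Without the replicate block the counts were 3 (CD8 T cells by anti-PD-1), 2 and 5 (regulatory T cells with 20 cells by genotype and by anti-PD-1), 0 (macrophages and monocytes by genotype), 2 (NK cells by genotype) and 105 (gated CD8 T cells). DESeq2 gave 4 (CD8 T cells), 1 and 1 (regulatory T cells with 20 cells), 39 and 4 (macrophages and monocytes by genotype and by anti-PD-1), 15, 5 and 2 (NK cells by genotype, by anti-PD-1 and interaction) and 103 (gated CD8 T cells). With no filter on low counts they were 23 and 17 (regulatory T cells, 8 cells), 151, 88 and 23 (macrophages and monocytes by genotype, anti-PD-1 and interaction), 113, 45 and 44 (NK cells, in the same order) and 267 (gated CD8 T cells). With equal numbers of cells, where fewer genes are tested, they were 25 (CD8 T cells), 13 (regulatory T cells by genotype, 20 cells), 1 (8 cells) and 1 (NK cells, interaction). The genes themselves changed more than these counts: with equal cells 17 passed in macrophages and monocytes by genotype, 5 of them among the 15, and 7 in NK cells by genotype, 2 of them among the 7. By anti-PD-1 1 gene passed in macrophages and monocytes, and it was not Pltp.

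The stricter cell filter gave 12 (regulatory T cells by genotype, 20 cells) and 1 (macrophages and monocytes by genotype). Leiden resolution 0.5 gave 9 and 11 (regulatory T cells with 20 cells) and 5 and 0 (macrophages and monocytes by genotype and by anti-PD-1). With doublets kept they were 0 and 1 (regulatory T cells with 20 cells) and 7 and 0 (macrophages and monocytes). Without proliferating clusters CD8 T cells had 39 genes. Under the CD8 marker gate Tnfrsf4 turned from 0.90 to -0.32 (adjusted p = 0.900), the only change of direction of a called value.

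Without barcodes that hold T cell UMIs the counts were 5 and 0 (macrophages and monocytes by genotype and by anti-PD-1), 0 and 2 (NK cells by genotype and interaction), and 5 and 0 lists (NK cells by genotype and by anti-PD-1). In NK cells this leaves out 87.3% of floxed and 87.5% of TKO cells, since these cells carry such transcripts themselves, and 3092 genes remain to be tested. With an estimated correlation the lists moved were 0 (CD8 T cells), 0 and 0 (macrophages and monocytes), 0 and 1 (NK cells by genotype and by anti-PD-1); fry gave 0, 0, 0, 2 and 0 in that order. The exact permutation test, adjusted over classes, called 0 classes by genotype; 3 classes had its smallest p of 0.0286, which became 0.0952. The seed difference of 0.04 in regulatory T cells ran from 0.00917 to 0.0637 without single libraries, and was -0.00966 in macrophages and monocytes and -0.0292 in NK cells. Of the alternatives of single named genes and lists, 5409 stayed the same, 506 no longer passed, 218 newly passed, 446 moved in value and 1 reversed.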

Other observations

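The tests of depth, T cell denominator, T cell RNA, clusters and mixed barcodes in this part were chosen after the results were seen; the counts over splits of the libraries were planned as a method, though not for NK cells, for regulatory T cells with 8 cells or for lists outside CD8 T cells.

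Some barcodes fell outside the named classes. A cluster of 127 barcodes with Ear2, Ace and Treml4, of which the last pair mark a kind of monocyte, made up 2.08% ± 0.826 of floxed and 0.988% ± 0.806 of TKO barcodes (SD, n = 4). A cluster of 76 barcodes with Gzmg and Gzmf, granzymes of late killer cells, made up 0.891% ± 0.299 and 0.963% ± 0.717. A cluster of 246 barcodes with globin transcripts and a median of 943 UMIs made up 4.49% ± 1.62 and 4.22% ± 2.26, and a further 96 barcodes with a median of 1112 UMIs 0.912% ± 0.529 and 1.90% ± 1.55. These differences were not tested.

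CD8 T cells were rarer in TKO libraries. Lower depth would shrink the difference once depth is made equal, but after thinning to 3000 UMIs the gated share was 7.86 times as high in floxed as in TKO libraries (23.2% ± 7.05 against 2.96% ± 1.67, SD, n = 4; exact permutation p = 0.0286). Without mixed barcodes, outside which lay 67 of the 147 gated TKO barcodes, it was 14.15 times as high after thinning and 12.02 times before. A general loss of T cells in dissociation or sorting would leave the CD8 share of T cells alike, yet its log2 fold change was -2.84 (adjusted p = 4.77e-05), although gated cells per regulatory T cell, 2.82 ± 1.09 against 0.706 ± 0.540, overlapped between the genotypes (exact permutation p = 0.0571). What lowers the CD8 share was not tested; tumour size, and day of processing if it followed genotype, are not in the labels and stay open.

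Interferon gamma genes were lower in TKO macrophages and monocytes. T cell RNA in these barcodes would take the difference with it, but 0.936 of the mean log2 fold change stayed without barcodes that hold T cell UMIs (-0.23, adjusted p = 6.65e-10). A shift between macrophage and monocyte clusters would leave little within them, but the mean within clusters was 1.31 times the pooled one, and below 0 in 5 of 5 clusters. Whether the scarcity of CD8 T cells is behind the pattern was not tested, and the list's call is lost with an estimated correlation (adjusted p = 0.243), so its strength rests on the correlation assumed.

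Barcodes with both lymphoid and myeloid transcripts numbered 814, or 5.71% to 15.7% of a library, against 0.267% to 1.59% expected as random doublets. The expected share takes the deposited barcodes as the cells captured and would be higher had more been captured. Random pairing would keep lymphoid partners in the ratio of the single cells, but partners with Foxp3 or the CD8 gate, per NK partner, exceeded it with an odds ratio of 3.65 to 8.20 over 8 libraries. Free myeloid RNA would leave depth as in macrophages, but the median UMIs of these barcodes were 1.54 to 2.69 times those of macrophages and monocytes of the same library. Attached cells, uptake and incomplete dissociation were not tested, so what these barcodes hold stays open.

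Every split of the 8 libraries into 4 and 4 was fitted in place of the real groups, 35 in all. Taken singly, chance can be excluded for the classes changed by genotype (1 class, highest of the other splits 0, 1 split as large, the real one). For genes of regulatory T cells by genotype with 8 cells the real split also had the highest count (6 genes, highest other 4, 1 split as large). Chance is not excluded there, since 8 genes left unchanged were called in the simulated data. Depth differed with genotype as well, and the splits cannot tell them apart. TKO libraries held 41031, 44229, 44238 and 120136 UMIs of these cells, and floxed libraries 113913 to 185225. Over the 12 results tested this way chance cannot be excluded for either result by the splits, since 1 of 35 is the smallest share they allow. The class result had an exact permutation p of 0.0952 adjusted over the classes, and of the 6 genes 1 stayed called without TKO PBS replicate 2. Chance cannot be excluded for genes of regulatory T cells by anti-PD-1 with 8 cells (1 gene; highest other 7; 24 splits as large), macrophages and monocytes by genotype (15; 16; 2) and by anti-PD-1 (1; 24; 10), or NK cells by genotype (7; 23; 3) and by anti-PD-1 (0; 30; 35). Nor can it for lists in macrophages and monocytes by genotype (9; 12; 11) and by anti-PD-1 (5; 12; 28), lists in NK cells by genotype (12; 13; 4) and by anti-PD-1 (7; 12; 4), or classes by anti-PD-1 (0; 1; 35). The other splits include the real split by the other factor and splits unbalanced over sex, so they do not hold chance alone. The split by sex also gave 7 genes in NK cells by genotype. The highest other count follows genotype for regulatory T cells by anti-PD-1 (7), lists in NK cells by anti-PD-1 (12) and classes by anti-PD-1 (1). In macrophages and in NK cells the highest counts of genes came from the split of the male floxed libraries, the male TKO PBS library and the female TKO anti-PD-1 library against the other 4, which points to a structure of the samples. In macrophages these are the 4 libraries with the most cells (335 to 896 against 103 to 261), and in NK cells the ranges overlap (107 to 393 against 53 to 227). Whether yield causes these counts was not tested.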
